A study of Homo sapiens with 12 samples.

How the data were processed

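Polyadenylated RNA was sequenced from 2 kinds of human endothelial cell (EC), lymphatic EC of the dermis (LEC) and EC of the coronary artery, each with vehicle or with deferoxamine (DFO), an iron chelator, for 24 h. The 4 groups of 3 libraries were taken from the sample titles. The dose was 100 uM per the labels, while the series description gives the same figure in mM, so the dose stays uncertain. Nothing in the labels says whether the 3 replicates of a group came from separate cultures or donors, so all p-values measure only the spread between these libraries, which may be technical.

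The deposited count table holds raw counts for 62710 Ensembl genes. The authors mapped paired-end reads of 150 bases to hg38 with STAR 2.7.9a and counted genes with featureCounts of Subread, per the submitters' processing notes and the series description. The annotation, the Subread version, the strand setting and whether reads or fragments were counted are not given in the sources used here. The authors' deposited normalized counts, a signal scale of counts divided by a single size factor per library, cover the 17141 genes whose total count over the 12 libraries exceeded 50. The authors' 2 deposited comparison tables give, per the file headers, a mean normalized count, a log2 fold change of DFO over control with its standard error, a Wald score, and a p-value with its adjusted p-value. The authors made them with DESeq2 1.34.0, per the submitters' processing notes.

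All tests here started from the deposited counts. Total counts per library ranged from 19179899 to 31611238. Gene names, biotypes and coordinates came from GENCODE 44 on hg38, in which 62639 gene IDs were found and 71 were not. The main test was edgeR 4.0.16 in R 4.3.3: filterByExpr by group, which kept 15952 genes, TMM scaling, and a quasi-likelihood F test in a model of all 12 libraries with a coefficient per group and no covariate. The 4 contrasts tested on it were DFO against control in LEC, the same in artery EC, the LEC effect minus the artery effect, and LEC control against artery EC control. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p below 0.05. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of its F statistic. This is an approximation that can be too small, above all for genes with few counts or a large change. The authors' deposited SE were larger for some genes, such as EGLN3 and PROX1 in LEC (0.73 and 0.26). CPM are counts scaled to a common total with the TMM factors, given as mean ± SD over 3 libraries. Genes that could tell a donor's sex were kept in the model and are not reported.

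Before the data were examined, 32 gene lists were fixed: iron handling, iron-sulfur and heme synthesis, hypoxia targets, glycolysis, nuclear and mitochondrially encoded oxidative phosphorylation, TCA cycle, DNA replication, mitosis, p53 targets, amino acid and ER stress, cholesterol synthesis, oxidative stress and ferroptosis, oxygen- and iron-dependent dioxygenases, the HIF pathway, arterial, lymphatic, venous and pan-endothelial identity, flow response, angiogenesis, BMP and TGF-beta targets, mesenchymal transition, extracellular matrix, inflammation, interferon response, autophagy and lysosome, ribosome biogenesis, and markers of smooth muscle cells, fibroblasts, keratinocytes with other epithelial cells, and leukocytes. The 29 lists with at least 5 tested members were tested with camera of limma 3.58.1, which compares a list with the other genes, on log CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the lists of a contrast. Camera was repeated with the correlation estimated per list. The lists share members, so their results are not independent. Members also on another list were 9 of 32 hypoxia targets, 10 of 30 dioxygenases, 4 of 11 HIF pathway, 15 of 27 angiogenesis and 11 of 32 matrix genes. The fry test asks whether a list's genes move, on balance, in a single direction (PValue) or change in either direction (PValue.Mixed), without comparing the list with other genes.

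The rule for naming genes was also fixed beforehand. It took, for each DFO contrast, the 8 called genes with the largest change each way at a mean CPM of at least 10 in a group and with all 3 DFO libraries on the same side of all 3 control libraries. It further took the 4 members of each list with the smallest p, and a set of genes always given. For the difference it took the 8 largest each way, and for the control comparison the 5 largest each way with the leading lymphatic and arterial members. List members that went against their list, and genes named because a count was small, were picked after their values were seen. Some genes that the naming rule picked are not reported here. For a gene with 0 counts in a group the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with its exact 95% interval. These intervals and floors cover counting error only.

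The tests were checked on simulated data drawn from each gene's mean over all 12 libraries and the real library sizes. Only 200 genes were changed, and no other difference between groups was kept. For LEC, among 15330 genes, 70.1%, 80.3% and 93.8% of genes changed 1.5-fold, 2-fold and 4-fold were called, with 10 unchanged genes called. For artery EC, among 15343 genes, the shares were 68.9%, 84.8% and 96.9%, with 12 unchanged genes called. For the difference, among 15339 genes, they were 31.7%, 65.1% and 81.0%, with 3 unchanged genes called. For the control comparison, among 15320 genes, they were 65.1%, 81.2% and 93.8%, with 14 unchanged genes called. Changes of 1.5-fold in the difference were therefore often missed in this simulation. In the real data 53.2% of genes were called in LEC, 63.1% in artery EC and 33.6% for the difference. The simulated shares need not hold there, and the shift in composition with DFO was not simulated.

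The alternatives tried were relative log expression (RLE) size factors, upper-quartile scaling, total counts without factors, no low-count filter, a filter of CPM at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, each comparison fitted alone, the replicate number as a block, an adjusted p below 0.01, a test against a 1.5-fold change, removal of mitochondrially encoded genes, and leaving out each library. Thinning every library to 19179899 counts was added after the depths were seen. Without a stated strand setting, reads of overlapping genes cannot be told apart. Of 719 genes on the lists or picked by the naming rule, 32 shared at least 20% of their exonic bases with a gene on the same strand and 37 with a gene on the opposite strand. The values of such genes, among them FTH1, CA9, HMGCS1, ICAM1, SQSTM1, NOB1, GJA5, CCL14, SDHA, ACE, SOX7, PRC1, AQP1 and MGARP, are uncertain. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.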

Results

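Deferoxamine binds iron and lowers the iron available to the cell, including that needed by enzymes that use iron and oxygen together. The series asked how iron depletion alters endothelial cells, and measured RNA in dermal lymphatic EC (LEC) and coronary artery EC grown to confluence, with 3 vehicle and 3 DFO libraries of each. Total counts were 20943989, 23359771 and 22134070 in LEC control, 20743173, 21711005 and 21170812 in LEC DFO, 31611238, 26959146 and 21730445 in artery control, and 19179899, 20486771 and 19644930 in artery DFO, so that 2 of the 3 artery control libraries were the deepest. The first principal component of log CPM held 61.4% of the variance and the second 30.9%. The 50 most abundant genes took 13.3% to 14% of counts in LEC control and 17.5% to 18% in LEC DFO, against 15.9% to 16.3% in artery control and 21.7% to 22.1% in artery DFO. No replicates were alike within sampling noise, with correlations of log CPM from 0.991 to 0.996. All adjusted p-values below are from edgeR's quasi-likelihood test or, for lists, from camera in limma.

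In LEC, DFO raised the transferrin receptor gene TFRC, through which cells import iron (ENSG00000072274, chromosome 3, 196012511 to 196082153, hg38), from 177 ± 9.4 to 560 ± 14 CPM (SD, n = 3), a log2 fold change of 1.66 ± 0.07 (SE; adjusted p = 9.06e-19). It lowered SLC40A1, which encodes the iron exporter ferroportin (ENSG00000138449, chromosome 2, 189560590 to 189583758), from 78.8 ± 15 to 27.1 ± 1.8 CPM (-1.54 ± 0.11, adjusted p = 1.53e-13). The heme-degrading oxygenase gene HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214) fell by 1.53 on the log2 scale (adjusted p = 6.07e-16), and the zinc and iron importer gene SLC39A14 rose by 1.0. Of the ferritin genes that store iron, FTL rose by 0.64, whereas FTH1 stood at 382 and 385 CPM (0.01 ± 0.09, adjusted p = 0.917; -0.25 and called under total counts), although 63.2% of the exonic bases of FTH1 overlap BEST1 on the opposite strand. Over the 23 tested iron handling genes, 9 rose, 8 fell and 6 did not pass (camera adjusted p = 0.966). In iron-sulfur and heme synthesis, 8 of 26 genes rose, 11 fell and 7 did not pass (adjusted p = 0.432). ALAS1, the first enzyme of heme synthesis, rose by 0.76, while UROD, a later enzyme of the same pathway, fell by 0.70. The counts of these lists adjusted over the list alone were the same.

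Genes that hypoxia-inducible factors (HIF) switch on rose in LEC with DFO. Of 32 hypoxia targets, 29 rose, none fell and 3 did not pass, both over all genes and adjusted over the list alone (median log2 fold change 2.14, adjusted p = 1.26e-19). VEGFA, the main growth factor for vessels (ENSG00000112715, chromosome 6, 43770184 to 43786487), rose from 4.33 to 62.4 CPM (3.84 ± 0.13, adjusted p = 6.32e-22). ANGPTL4, an inhibitor of lipoprotein lipase, rose from 2.49 to 174 CPM (6.13 ± 0.11, adjusted p = 4.18e-28), and EGLN3, a prolyl hydroxylase that marks HIF for degradation, rose from 0.0541 to 64.8 CPM (10.07 ± 0.30, adjusted p = 1.09e-24). The control level of EGLN3 was near the floor of 0.0411 CPM for 3 counts in that group, and the authors' deposited SE was 0.73. The 3 members that did not pass were CA9, with 0 counts in both LEC groups, HILPDA (0.18) and WSB1 (0.17). PPFIA4 had 0 counts in control and 153 with DFO and was at least 64-fold higher. With CA9 left out and PPFIA4 at its bound, the list's median was 2.18. Of 21 glycolysis genes, 20 rose and PFKM fell by 0.19, over all genes and adjusted over the list alone (median 1.19, adjusted p = 6.43e-14). The glucose transporter gene SLC2A1 rose from 27.5 to 371 CPM (3.75 ± 0.08, adjusted p = 5.02e-26), and LDHA, which makes lactate, rose by 1.62.

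Among 30 dioxygenases that use oxygen and iron, 21 rose and 3 fell (TET1, KDM3B and FTO), with 21 and 4 when adjusted over the list alone (median 0.58, adjusted p = 3.08e-06). The collagen hydroxylase genes P4HA1, P4HA2 and PLOD2 rose by 3.80, 2.40 and 2.48. In the HIF pathway, 6 of 11 genes rose and HIF1A, which encodes the oxygen-regulated subunit, fell by 1.43, with the same counts adjusted over the list alone (adjusted p = 0.0426, and adjusted p = 0.0921 with an estimated correlation). That call was also lost without DFO replicate 1 (adjusted p = 0.0606), with thinned libraries (0.0509), with the CPM filter (0.0661) and with LEC fitted alone (0.111). Of 35 nuclear oxidative phosphorylation genes, 6 rose, 5 fell and 24 did not pass, or 5 and 3 adjusted over the list alone, and their median changed sign under upper-quartile and total-count scaling (adjusted p = 0.808). Of 13 mitochondrially encoded genes, 9 rose and MT-ND3 and MT-CO2 fell, with the same counts adjusted over the list alone (adjusted p = 0.198). These genes took 2.07% to 2.56% of counts in control and 2.96% to 3.43% with DFO. In the TCA cycle, 5 of 18 genes rose and 6 fell, also adjusted over the list alone (adjusted p = 0.936): OGDH fell by 1.43 and IDH2 rose by 1.28.

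Genes of mitosis fell in LEC. Of 28 members, 27 fell and CDK1 rose by 0.23, over all genes and adjusted over the list alone (median -1.33, adjusted p = 1.13e-12). KIF20A, a kinesin of cell division, fell from 99.3 to 11.7 CPM (-3.08 ± 0.11, adjusted p = 1.05e-20), and the proliferation marker MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126423) fell from 306 to 171 CPM (-0.84 ± 0.09, adjusted p = 3.21e-09). DNA replication genes split: 11 of 28 rose and 7 fell, or 11 and 8 adjusted over the list alone, around a median of 0.04 that turned negative under upper-quartile and total-count scaling (adjusted p = 0.471). RRM2, the iron-dependent subunit of ribonucleotide reductase (ENSG00000171848, chromosome 2, 10120698 to 10211725), rose from 106 ± 7.0 to 278 ± 20 CPM (1.39 ± 0.08, adjusted p = 5.85e-16), and the licensing factor gene CDT1 rose by 1.66, while MCM6, part of the replicative helicase, fell by 1.15. Of 25 p53 targets, 24 rose and ZMAT3 did not pass, also adjusted over the list alone (median 1.36, adjusted p = 2.42e-13). CDKN1A, the cell-cycle inhibitor p21 (ENSG00000124762, chromosome 6, 36676460 to 36687337), rose from 208 to 975 CPM (2.23 ± 0.07, adjusted p = 5.61e-23), and GDF15 rose by 3.22. Of 23 ribosome biogenesis genes, 12 fell, among them DKC1 (-1.21) and UTP20 (-1.47), and 4 rose (MYC, NPM1, RRP12 and NOB1), also adjusted over the list alone (adjusted p = 0.00327, and adjusted p = 0.104 with an estimated correlation).

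Of 22 genes of amino acid and endoplasmic reticulum (ER) stress, 21 rose and the cystine transporter gene SLC7A11 fell by 0.84, also adjusted over the list alone (median 1.58, adjusted p = 3.44e-12). The ER chaperone gene HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241382) rose from 869 to 2890 CPM (1.73 ± 0.07, adjusted p = 2.59e-19), HSP90B1 rose by 1.93 and the stress-induced transcription factor gene ATF3 by 7.21. In cholesterol synthesis, 12 of 24 genes fell and 5 rose, or 12 and 6 adjusted over the list alone (median -0.25, adjusted p = 0.183). Of 26 autophagy and lysosome genes, 17 rose, with NPC1 (1.11) and SQSTM1 (0.80) among them, and 2 fell, CTSL included, also adjusted over the list alone (median 0.43, adjusted p = 0.000317, and adjusted p = 0.0785 with an estimated correlation). In oxidative stress and ferroptosis, 7 of 22 rose and 7 fell, or 8 and 7 adjusted over the list alone (adjusted p = 0.815). SOD2, the mitochondrial superoxide dismutase, rose by 1.83. The sign of this list's median turned under upper-quartile and total-count scaling.

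Genes of lymphatic identity went both ways. PROX1, the transcription factor that specifies lymphatic endothelium (ENSG00000117707, chromosome 1, 213983181 to 214041510), fell from 177 ± 41 to 90.8 ± 19 CPM (-0.96 ± 0.12, adjusted p = 4.75e-08). The authors' deposited SE for PROX1 was 0.26. LYVE1, a hyaluronan receptor, fell by 1.77 and NR2F2, which acts with PROX1, by 1.16, while ANGPT2 rose by 2.09 and FLT4, the receptor of VEGF-C, by 0.33 (0.06 and not called under total counts). In all, 7 of 20 lymphatic genes rose and 9 fell (adjusted p = 0.709), 2 of 10 venous genes rose (NRP2 and VWF) and 6 fell (adjusted p = 0.167), and 14 of 26 arterial genes rose and 6 fell (adjusted p = 0.125), with the same counts adjusted over the list alone. Arterial genes that rose included the Notch ligand gene DLL4 (2.37), CXCR4 (2.27) and SOX17 (1.41), and HEY1, a Notch target, fell by 1.55. Of 24 pan-endothelial genes, 12 rose and 10 fell, or 12 and 11 adjusted over the list alone, around a median of 0.14 that turned negative under total counts (adjusted p = 0.821). The junction genes PECAM1 and CDH5 rose by 0.76 and 0.64, CLDN5 fell by 1.21, and KDR, the main VEGF receptor gene, fell by 0.56.

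Of 26 angiogenesis genes in LEC, 23 rose and KDR and ANGPT1 fell (median 1.10, adjusted p = 2.64e-09), with FLT1, a decoy VEGF receptor, up by 3.45 and PGF by 1.84. Of 22 flow-response genes, 11 rose and NOS3, ACE, AQP1 and PROCR fell (adjusted p = 0.0337, and adjusted p = 0.0745 with an estimated correlation or 0.0691 with LEC fitted alone). NOS3, the endothelial nitric oxide synthase gene (ENSG00000164867, chromosome 7, 150991017 to 151014588), fell from 107 to 57.6 CPM (-0.89 ± 0.09, adjusted p = 3.52e-10), and KLF2, a flow-induced factor, did not pass (-0.20 ± 0.15, adjusted p = 0.281), but did under total counts (-0.46, adjusted p = 0.00873). BMP and TGF-beta targets rose in 18 of 25 cases and fell in 5 (ID1, ID3, SMAD9, HEY1 and ATOH8; adjusted p = 0.000391), with the matricellular gene CCN2 up by 1.67. Of 32 extracellular matrix genes, 24 rose, among them LOX (1.73), and COL8A1 fell (median 0.80, adjusted p = 1.02e-09). Of 19 mesenchymal transition genes, 10 rose, with FN1 (1.55) and SNAI2 (1.62), and 5 fell (adjusted p = 0.123). Of 25 inflammation genes, 13 rose, with CXCL8 (3.58) and TNFAIP3 (4.42), and SELP, CXCL1, IL33 and CSF3 fell (adjusted p = 0.000507). Of 29 interferon-response genes, 7 rose and 7 fell (adjusted p = 0.595), and the list's median of 0.16 turned negative under total counts. All counts in this paragraph were the same adjusted over the list alone.

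Markers of other cell types were low or mixed in LEC. Of 7 tested smooth muscle markers, 4 rose and none fell (adjusted p = 0.12): SMTN, which EC also express, went from 109 to 145 CPM (not called under total counts, 0.13), NOTCH3 from 3 to 32 counts (13.4-fold, 95% interval 4.19 to 68.4), and CSPG4 and ITGA8 stayed at 0.637 and 1.79 CPM or below. The call of CSPG4 was lost without control replicate 3 (1.59), and that of ITGA8 without control replicate 3 (0.73) or DFO replicate 1 (0.84) or 3 (0.97). CSPG4 was also not called with DESeq2 (adjusted p = 0.0509) or in the authors' table (0.0535), nor ITGA8 under total counts (0.78, adjusted p = 0.0919). Of 4 fibroblast markers, COL1A2 fell by 0.91, from 14.1 CPM, and the other members did not pass. Under total counts PI16 (-1.07) and the epithelial keratin genes KRT8 (-0.31) and KRT18 (-0.21) passed as lower. Of 4 tested keratinocyte and epithelial markers, DSP rose by 1.38 and KRT10 fell by 1.22. The list's keratin genes KRT5, KRT14 and KRT1 had 0 counts in every group. FCER1G, the only tested leukocyte marker of the list, stood at 0.547 and 0.361 CPM and did not pass. Counts adjusted over the list alone were the same.

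In total, 4243 genes rose and 4247 fell in LEC with DFO, and 7462 of 15952 did not pass, with 1090 and 1385 changed at least 2-fold. The genes with the largest increases by the naming rule were EGLN3, ATF3, AK4, NR4A1, ANGPTL4, MYH16, RRAD and NPTX1, and those with the largest decreases included APOL4, KIF20A, ZSCAN31, CCNA1, GIPC2, ELOVL6 and ANKRD55 (log2 fold changes of -3.42 to -2.85). The balance of directions depended on the scaling: with total counts 2406 rose and 6701 fell, 26.4% higher in place of 50%, because the median gene then stood at -0.28, and changes here are relative to the TMM median of -0.01. Of 14 lists called by camera in LEC, 10 held with an estimated correlation.

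In artery EC, the iron genes included changes of the same kind. TFRC rose from 212 to 521 CPM (1.30 ± 0.07, adjusted p = 1.42e-16), and SLC40A1 fell from 13.7 to 4.76 CPM (-1.53 ± 0.17, adjusted p = 4.34e-09). FTL and FTH1 rose by 0.86 and 0.66, the mitochondrial iron importer gene SLC25A37 rose by 1.85, and FBXL5, the iron sensor that tags iron regulatory protein for degradation, fell by 0.79. In all, 10 of 23 iron handling genes rose and 11 fell (adjusted p = 0.873). Iron-sulfur and heme synthesis genes fell in 17 of 26 cases, with IBA57, ALAS1 and CPOX higher (median -0.37, adjusted p = 0.00389, and adjusted p = 0.0535 with an estimated correlation). FECH, which inserts iron into heme, fell by 1.33. Counts adjusted over the list alone were the same for both lists.

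All 32 hypoxia targets rose in artery EC, also adjusted over the list alone (median 3.25, adjusted p = 1.07e-21). NDRG1, a growth-arrest gene induced by iron chelators (ENSG00000104419, chromosome 8, 133237175 to 133302022), rose from 15.1 to 1120 CPM (6.21 ± 0.09, adjusted p = 6.86e-32), and VEGFA rose from 8.73 to 213 CPM (4.60 ± 0.10, adjusted p = 1.78e-26). EGLN3 rose by 7.93 and PPFIA4 by 9.12. CA9, a carbonic anhydrase that regulates pH in hypoxia, went from 2 to 734 counts, a 649-fold increase with a 95% interval of 179 to 5370, although 35.7% of its exonic bases overlap ARHGEF39 on the opposite strand. Of 21 glycolysis genes, 20 rose, with ENO2 at 5.68 and SLC2A1 at 4.59, and PFKM fell by 0.51 (median 1.70, adjusted p = 5.24e-12, and adjusted p = 0.0535 with an estimated correlation). Of 30 dioxygenases, 27 rose, KDM3A by 3.49 and P4HA1 by 4.69 among them, and the RNA demethylase gene FTO fell (median 0.94, adjusted p = 3.26e-10). In the HIF pathway, 9 of 11 genes rose and HIF1A fell by 1.58 (adjusted p = 0.00718, and adjusted p = 0.0595 with an estimated correlation). These counts were the same adjusted over the list alone.

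Of 35 nuclear oxidative phosphorylation genes, 24 fell and SDHA and COX4I1 rose in artery EC, or 25 and 2 adjusted over the list alone (median -0.44, adjusted p = 7.91e-05, and adjusted p = 0.233 with an estimated correlation). ATP5MC1, a subunit of the ATP synthase ring, fell from 61.7 to 13.8 CPM (-2.16 ± 0.11, adjusted p = 4.78e-17), and NDUFB10 and NDUFS8 of complex I fell by 1.06 each. In the TCA cycle, 13 of 18 genes fell, OGDH by 1.21 and FH by 1.09, and IDH2 and DLST rose, also adjusted over the list alone (adjusted p = 0.00287, and adjusted p = 0.348 with an estimated correlation). Of 13 mitochondrially encoded genes, 6 rose and MT-CO2 and MT-CO3 fell, also adjusted over the list alone (adjusted p = 0.445), and the list's median of 0.20 turned negative under total counts, where MT-ND5 and MT-CO1 stood at -0.032 and -0.11. These genes took 2.52% to 2.68% of counts in control and 2.97% to 3.59% with DFO.

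All 28 mitosis genes and all 28 DNA replication genes tested fell in artery EC, also adjusted over the list alone (medians -3.53 and -1.52, adjusted p = 6.34e-19 and 5.24e-12). CDC20, which activates the anaphase-promoting complex, fell from 120 to 3.54 CPM (-5.07 ± 0.13, adjusted p = 3.82e-25), TOP2A (topoisomerase II alpha) fell by 4.33, and MKI67 fell from 178 to 36.9 CPM (-2.27 ± 0.10, adjusted p = 1.88e-18). UHRF1, which maintains DNA methylation at replication, fell by 3.0, MCM6 by 2.48, and RRM2 from 140 ± 6.9 to 72.4 ± 7.3 CPM (-0.95 ± 0.08, adjusted p = 7.14e-12). Of 25 p53 targets, 19 rose, with GDF15 at 2.36 and CDKN1A at 1.70, and BAX and TP53I3 fell (median 0.73, adjusted p = 1.13e-05, and adjusted p = 0.0612 with an estimated correlation). Ribosome biogenesis genes fell in 17 of 23 cases, with DKC1 at -1.41 and NCL (nucleolin) at -0.86, and MYC and RRP12 rose (adjusted p = 0.000135, and adjusted p = 0.0595 with an estimated correlation). Both lists had the same counts adjusted over the list alone.

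Cholesterol synthesis genes rose in 18 of 24 cases in artery EC, 2 fell, among them PMVK, and 4 did not pass (median 0.87, adjusted p = 2.18e-05, and adjusted p = 0.186 with an estimated correlation). SREBF2, the pathway's transcription factor, rose by 1.62 and INSIG1 by 1.82. Of 22 amino acid and ER stress genes, 18 rose, with ATF3 at 5.97 and VLDLR at 3.46, and the ER chaperone genes HSPA5, SDF2L1 and CRELD2 fell (median 0.90, adjusted p = 1.44e-05, and adjusted p = 0.0612 with an estimated correlation). Autophagy and lysosome genes rose in 18 of 26 cases, with NPC1 at 2.59 and MAP1LC3B at 1.70, and 3 fell, CTSL included (median 0.78, adjusted p = 0.000125, and adjusted p = 0.0619 with an estimated correlation). In oxidative stress and ferroptosis, 10 of 22 rose and 8 fell (adjusted p = 0.694), with SOD2 at 1.55 and NQO1 at -1.70, around a median of 0.10 that turned negative under total counts. All 4 lists had the same counts adjusted over the list alone.

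Arterial identity genes rose in 20 of 26 cases in artery EC (median 0.54, adjusted p = 0.00258, and adjusted p = 0.253 with an estimated correlation), with IGFBP3 at 2.92 and CXCR4 at 1.86. The 5 that fell were the gap junction genes GJA4 (-3.75) and GJA5, the kinase gene BMX (-2.58), SOX18 and HEY2. Of 10 venous genes, 5 fell, FLRT2 by 2.72 and NR2F2 by 1.70 among them, and NRP2, VWF and POSTN rose (adjusted p = 0.245). Of 20 lymphatic genes, 6 rose and LYVE1, FOXC2, CLDN11 and NR2F2 fell (adjusted p = 0.955). This list's mean of -0.14 and median of 0.04, 0.11 with genes of few counts left out, differed in sign, the test pointed up, and the median turned negative under total counts. PROX1 was at 2.78 and 2.39 CPM and did not pass (-0.20 ± 0.35, adjusted p = 0.64). Of 24 pan-endothelial genes, 15 rose, with ETS1 at 1.95 and CDH5 at 1.13, and 7 fell, CLEC14A by 1.13, around a median of 0.29 that turned negative under total counts (adjusted p = 0.0832). KDR passed narrowly (0.19 ± 0.08, adjusted p = 0.0497) and lost its call without control replicate 1, 2 or 3 (0.21, 0.15 and 0.20) or without DFO replicate 1 (0.10). KDR was also not called with upper-quartile scaling (0.096), with DESeq2 (adjusted p = 0.0502) or in the authors' table (0.0576), and was called as lower under total counts (-0.20, adjusted p = 0.0256). FLT4 rose by 0.29, with a call lost without control replicate 2 (0.21) or DFO replicate 3 (0.23) or with upper-quartile scaling (0.20, adjusted p = 0.0881), and a value of -0.092 under total counts. Counts adjusted over the list alone were the same for these 4 lists.

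Angiogenesis genes rose in 22 of 26 cases in artery EC and ANGPT1 and ADAMTS1 fell (median 1.05, adjusted p = 5.46e-06, and adjusted p = 0.0838 with an estimated correlation), with PGF at 2.17 and FLT1 at 2.64. Of 22 flow-response genes, 11 rose and 5 fell (adjusted p = 0.195), AQP1 by 3.76 and NOS3 by 1.57, around a median of 0.30 that turned negative under total counts, and KLF2 did not pass (0.24 ± 0.13, adjusted p = 0.113), but did without control replicate 1 (0.41) or DFO replicate 2 (0.39). BMP and TGF-beta targets rose in 16 of 25 cases and fell in 6 (median 0.55, or 0.61 with the few-count gene GREM1 left out, adjusted p = 0.0136, and adjusted p = 0.0595 with an estimated correlation). The BMP antagonist gene NOG rose by 4.66 and the inhibitory gene SMAD6 by 2.50. Of 32 extracellular matrix genes, 24 rose, LOX by 2.53 and PLOD2 by 2.56, and COL8A1 and ADAMTS1 fell (median 1.02, adjusted p = 3.29e-07, and adjusted p = 0.0535 with an estimated correlation). Of 19 mesenchymal transition genes, 9 rose and 7 fell (adjusted p = 0.391), with VIM at 1.09 and MYL9 at -0.91, around a median of 0.21 that turned negative under total counts. Of 25 inflammation genes, 14 rose, ICAM1 by 1.78 and CXCL8 by 3.29, and 6 fell (median 0.56, adjusted p = 0.0352, and adjusted p = 0.115 with an estimated correlation; 0.0587 without DFO replicate 2, 0.0628 with the CPM filter and 0.055 with artery EC fitted alone). In the interferon response, 5 of 29 genes rose, among them ISG20 and IRF7, and 10 fell (adjusted p = 0.955). Counts adjusted over the list alone were the same throughout.

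Among markers of other cell types in artery EC, 4 of 7 smooth muscle genes rose (SMTN, NOTCH3, CSPG4 and ITGA8) and the pericyte gene RGS5 fell from 199 to 107 CPM (adjusted p = 0.391). All 4 fibroblast markers were lower with DFO: COL1A2 fell by 0.85 from 18.1 CPM, PI16 went from 26 to 0 counts and was at least 4.9-fold lower, and THY1 and COL3A1 stood below 1 CPM in both groups, the latter with an adjusted p of 0.0475. The COL3A1 call was lost without control replicate 1 (-1.21) or 3 (-1.31) or DFO replicate 1 (-0.98) or 2 (-1.0), and that of THY1 without control replicate 1 (-1.53) or 3 (-1.40) or DFO replicate 2 (-1.66) or 3 (-1.12). With DESeq2 neither was called (adjusted p = 0.162 and 0.0919), nor in the authors' table (0.167 and 0.0959), and COL3A1 was also lost with RLE size factors (0.0503) and without the low-count filter (0.0517). Of 4 keratinocyte and epithelial markers, KRT10 fell by 0.34 and KRT18 by 0.25, the latter not called without DFO replicate 1 (-0.19). KRT8 (0.22) and DSP did not pass, but KRT8 did without DFO replicate 2 (0.37) and DSP without control replicate 1 (1.93), with DESeq2 (adjusted p = 0.00407) and in the authors' table (0.00445). The leukocyte marker FCER1G did not pass. Counts adjusted over the list alone were the same.

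In total, 5127 genes rose and 4938 fell in artery EC with DFO, and 5887 did not pass, with 1771 and 2071 changed at least 2-fold. The largest increases by the naming rule were in PPFIA4, CA9, EGLN3, MIR210HG, NDRG1, ATF3, ENO2 and PFKFB4, and the largest decreases in DEPDC1, CDC20, PLK1, KIF20A, DLGAP5, SPC25, STEAP1 and ASPM, from -5.31 to -4.59. With total counts 2788 rose and 7657 fell, 26.7% higher in place of 50.9%, with the median gene at -0.38, and 114 of the calls took the opposite direction. Of 19 lists called by camera, 4 held with an estimated correlation.

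**Figure D1:**
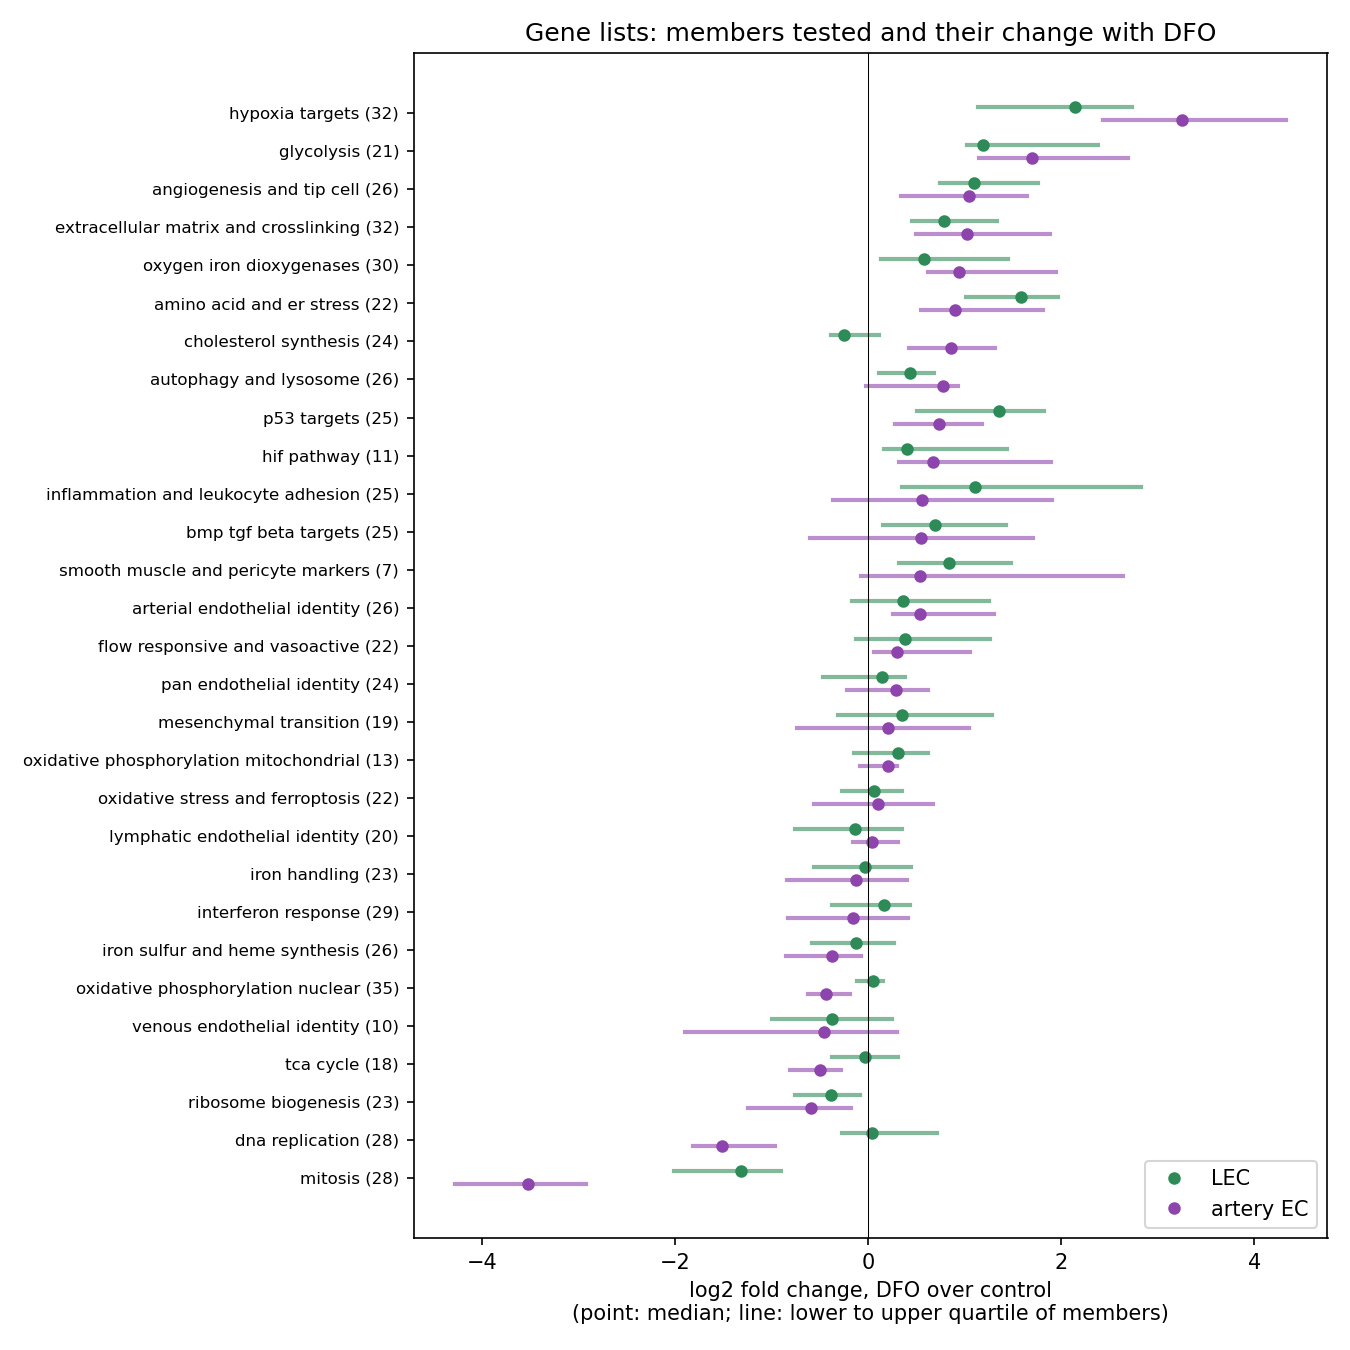
Change with DFO of the 29 lists that had at least 5 tested members (number tested in brackets), as log2 fold change over control in LEC (green) and artery EC (purple), with points at the median and lines from the lower to the upper quartile of members. Hypoxia targets were the highest list in both cell types (2.14 and 3.25) and mitosis the lowest (-1.33 and -3.53), while under total counts the medians of 5 lists in LEC (nuclear oxidative phosphorylation, DNA replication, oxidative stress, pan-endothelial, interferon) and 6 in artery EC (mitochondrially encoded, oxidative stress, lymphatic, pan-endothelial, flow, mesenchymal) change sign.

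The difference of the responses was tested directly, as the LEC effect minus the artery effect, so that positive values mean a higher value, or a smaller decrease, in LEC. The division genes differed most. All 28 DNA replication genes and 27 of 28 mitosis genes had a higher effect in LEC, also adjusted over the list alone (medians 1.5 and 2.08, or 2.07 for mitosis with few-count genes left out, adjusted p = 1.31e-21 and 6.88e-23), and PRC1 did not pass. RRM2 rose in LEC and fell in artery EC (difference 2.34 ± 0.11, adjusted p = 1.99e-16), as did CDT1 (2.04). Hypoxia targets rose further in artery EC in 25 of 32 cases, and ANGPTL4 and DDIT4 further in LEC, or 25 and 3 adjusted over the list alone (median -1.03, adjusted p = 5.53e-13). NDRG1 differed by -3.80 ± 0.11 (adjusted p = 1.44e-22) and VEGFA by -0.77, whereas TFRC had a difference of 0.36 ± 0.10 (adjusted p = 0.00549) and SLC40A1 of -0.01 ± 0.23 (adjusted p = 0.98).

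Cholesterol synthesis genes had a higher effect in artery EC in 20 of 24 cases and in none a lower one, or 22 and none adjusted over the list alone (median -0.89, adjusted p = 5.78e-11, and adjusted p = 0.106 with an estimated correlation). HMGCS1 (ENSG00000112972, chromosome 5, 43287470 to 43313512), whose exonic bases overlap an opposite-strand transcript by 37.7%, went from 78.7 to 54.1 CPM in LEC and from 49.2 to 118 in artery EC (-1.80 ± 0.12, adjusted p = 2.68e-13). INSIG1 and SQLE also moved in opposite directions (differences of -2.10 and -1.68). Dioxygenases rose further in artery EC in 18 of 30 cases, also adjusted over the list alone (median -0.59, adjusted p = 8.32e-07), and glycolysis genes in 14 of 21, with 3 the other way (PFKM, PGM1 and PGAM1), or 15 and 4 adjusted over the list alone (adjusted p = 0.000974, and adjusted p = 0.301 with an estimated correlation). Nuclear oxidative phosphorylation genes were relatively higher in LEC in 21 of 35 cases, or 26 adjusted over the list alone (adjusted p = 1.57e-07, and adjusted p = 0.181 with an estimated correlation), as were 9 of 18 TCA cycle genes, or 12 adjusted over the list alone (adjusted p = 0.000114, and adjusted p = 0.301 with an estimated correlation). ATP5MC1 differed by 1.72.

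P53 targets were relatively higher in LEC in 17 of 25 cases and lower in 2 (TP53INP1 and TNFRSF10B), also adjusted over the list alone (adjusted p = 1.64e-05, and adjusted p = 0.106 with an estimated correlation). Iron-sulfur and heme synthesis genes were so in 12 of 26 cases against 2 (IBA57 and CPOX), or 14 against 2 adjusted over the list alone (adjusted p = 0.00411, and adjusted p = 0.0647 with an estimated correlation), and ribosome biogenesis genes in 7 of 23 against none, also adjusted over the list alone (adjusted p = 0.0155, and adjusted p = 0.227 with an estimated correlation; 0.0502 without LEC control replicate 1). Autophagy and lysosome genes were relatively higher in artery EC in 13 of 26 cases against 3, or 16 against 3 adjusted over the list alone (adjusted p = 0.00321, and adjusted p = 0.181 with an estimated correlation), and matrix genes in 13 of 32 against 3, also adjusted over the list alone (adjusted p = 0.0218, and adjusted p = 0.309 with an estimated correlation; 0.0649 without artery DFO replicate 1 and 0.0546 without artery control replicate 2). Inflammation genes were relatively higher in LEC in 6 of 25 cases, also adjusted over the list alone (adjusted p = 0.0488, and adjusted p = 0.181 with an estimated correlation), a call lost in most alternatives. It was lost without artery DFO replicate 1 or 3 (0.0827 and 0.0593), artery control replicate 2 or 3 (0.0596 and 0.0504), LEC DFO replicate 1 or 2 (0.0527 and 0.0629) or LEC control replicate 1 (0.0743). The median of 0.50 was 0.23 without artery control replicate 2 and 0.27 without LEC DFO replicate 2, and the matrix median of -0.12 was -0.079 without artery DFO replicate 1 and -0.09 without artery control replicate 2.

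The ER stress list did not pass for the difference (10 genes higher and 6 lower of 22, or 10 and 7 adjusted over the list alone, adjusted p = 0.0529), although HSPA5 rose in LEC and fell in artery EC (2.17 ± 0.10, adjusted p = 7.57e-17). Pan-endothelial genes did not either (6 higher and 11 lower of 24, or 6 and 12 adjusted over the list alone, adjusted p = 0.0529). Both lists passed without artery DFO replicate 2 (0.0352 for ER stress and 0.0346), LEC DFO replicate 1 (0.0491 and 0.0483) or LEC control replicate 2 (0.0395 for each) or 3 (0.0377 and 0.0384), and the pan-endothelial list also without artery control replicate 1 (0.0396). No difference was called for iron handling, mitochondrially encoded genes, oxidative stress, the HIF pathway, arterial, lymphatic and venous identity, flow response, angiogenesis, BMP and TGF-beta targets, mesenchymal transition, interferon response and smooth muscle markers, with adjusted p-values from 0.245 to 0.96. For iron handling the median (0.14) and mean (-0.03) differed in sign, and for lymphatic identity (-0.16), interferon response (0.07) and smooth muscle markers (-0.09) the test pointed against the median. HMOX1 (-1.90 ± 0.12, adjusted p = 4.84e-14) fell in LEC and rose in artery EC, and CCN2 (ENSG00000118523, chromosome 6, 131948176 to 131951372) rose in LEC and fell in artery EC (2.40 ± 0.10, adjusted p = 2.56e-17). The artery rise of HMOX1 (0.36) is no larger than the shift of the median artery gene under total counts (-0.38), so that rise depends on the scaling. The largest differences toward LEC were in MGARP, TMEM171, DEPDC1, SPC25, DKK1, FST, ABCB1 and UBE2C, and toward artery EC in KBTBD11, SLITRK4, MIR210HG, SYTL2, NDRG1, KCTD16, ZSWIM5 and DTNA. In LEC, ABCB1 went from 2 to 15 counts (9.42-fold, 95% interval 2.19 to 84.9) and SLITRK4 from 7 to 0 counts (at least 1.81-fold lower), and in artery EC KBTBD11 went from 2 to 48 counts (42.4-fold, 95% interval 11.1 to 361). The call of ABCB1 was lost without LEC DFO replicate 1 or 2 or LEC control replicate 2 or 3 (adjusted p from 0.0572 to 0.161), and that of SLITRK4 without any library other than LEC control replicate 1 and artery DFO replicate 3 (0.0521 to 0.257), and in 6 other settings (0.051 to 0.116). Altogether 5356 genes differed, 2770 with a higher and 2586 with a lower effect in LEC, and 4 of 14 called lists held with an estimated correlation. With total counts the median difference was 0.10, and 3642 genes had a higher and 1897 a lower effect in LEC.

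**Figure D2:**
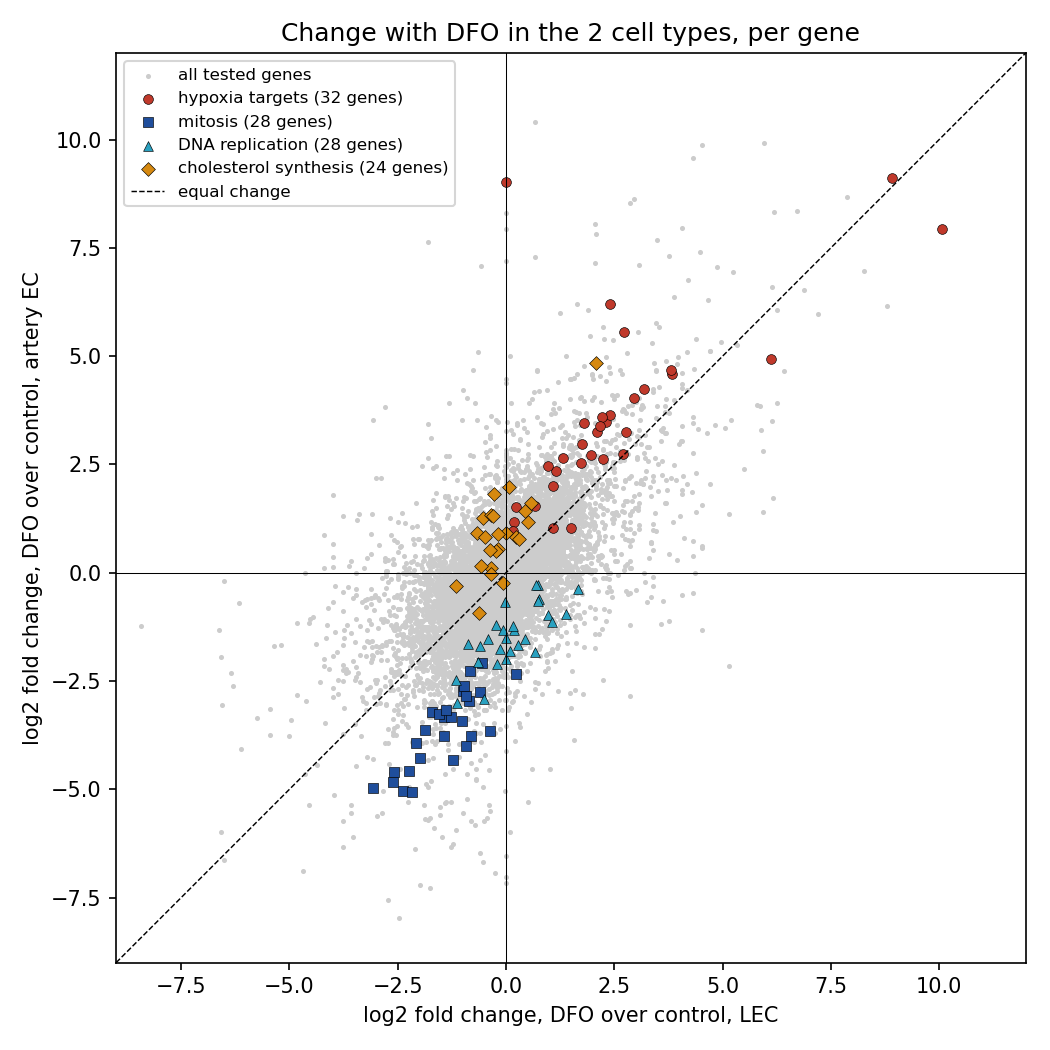
Log2 fold change with DFO in LEC (x axis) and artery EC (y axis) for 15934 genes, with members of 4 lists coloured and the line of equal change dashed. Hypoxia targets lie mostly above the line (median difference -1.03) and mitosis and DNA replication genes below it (2.08 and 1.5). The points of CA9 and PPFIA4 rest on 0 to 4 counts in some groups, and the DNA replication median in LEC turns negative under upper-quartile and total-count scaling.

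The responses of the cell types overlapped. In the same direction, 5938 genes were called in both, 3146 higher and 2792 lower, against 1364 and 1315 for independent lists, and 601 were called in opposite directions. These comparisons share no library. Across the 15952 genes, which are not independent replicates, the fold changes correlated with Pearson's r = 0.606 and Spearman's rho = 0.607 (r = 0.241 without the low-count filter). Among the 5938 genes the change was larger in artery EC for 3882 and larger in LEC for 2056, and the difference itself was called for 1674 and 442 of them. Of 1951 genes called in LEC and not in artery EC, the difference was called for 821, and of 3526 called in artery EC and not in LEC, for 1740.

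**Figure D3:**
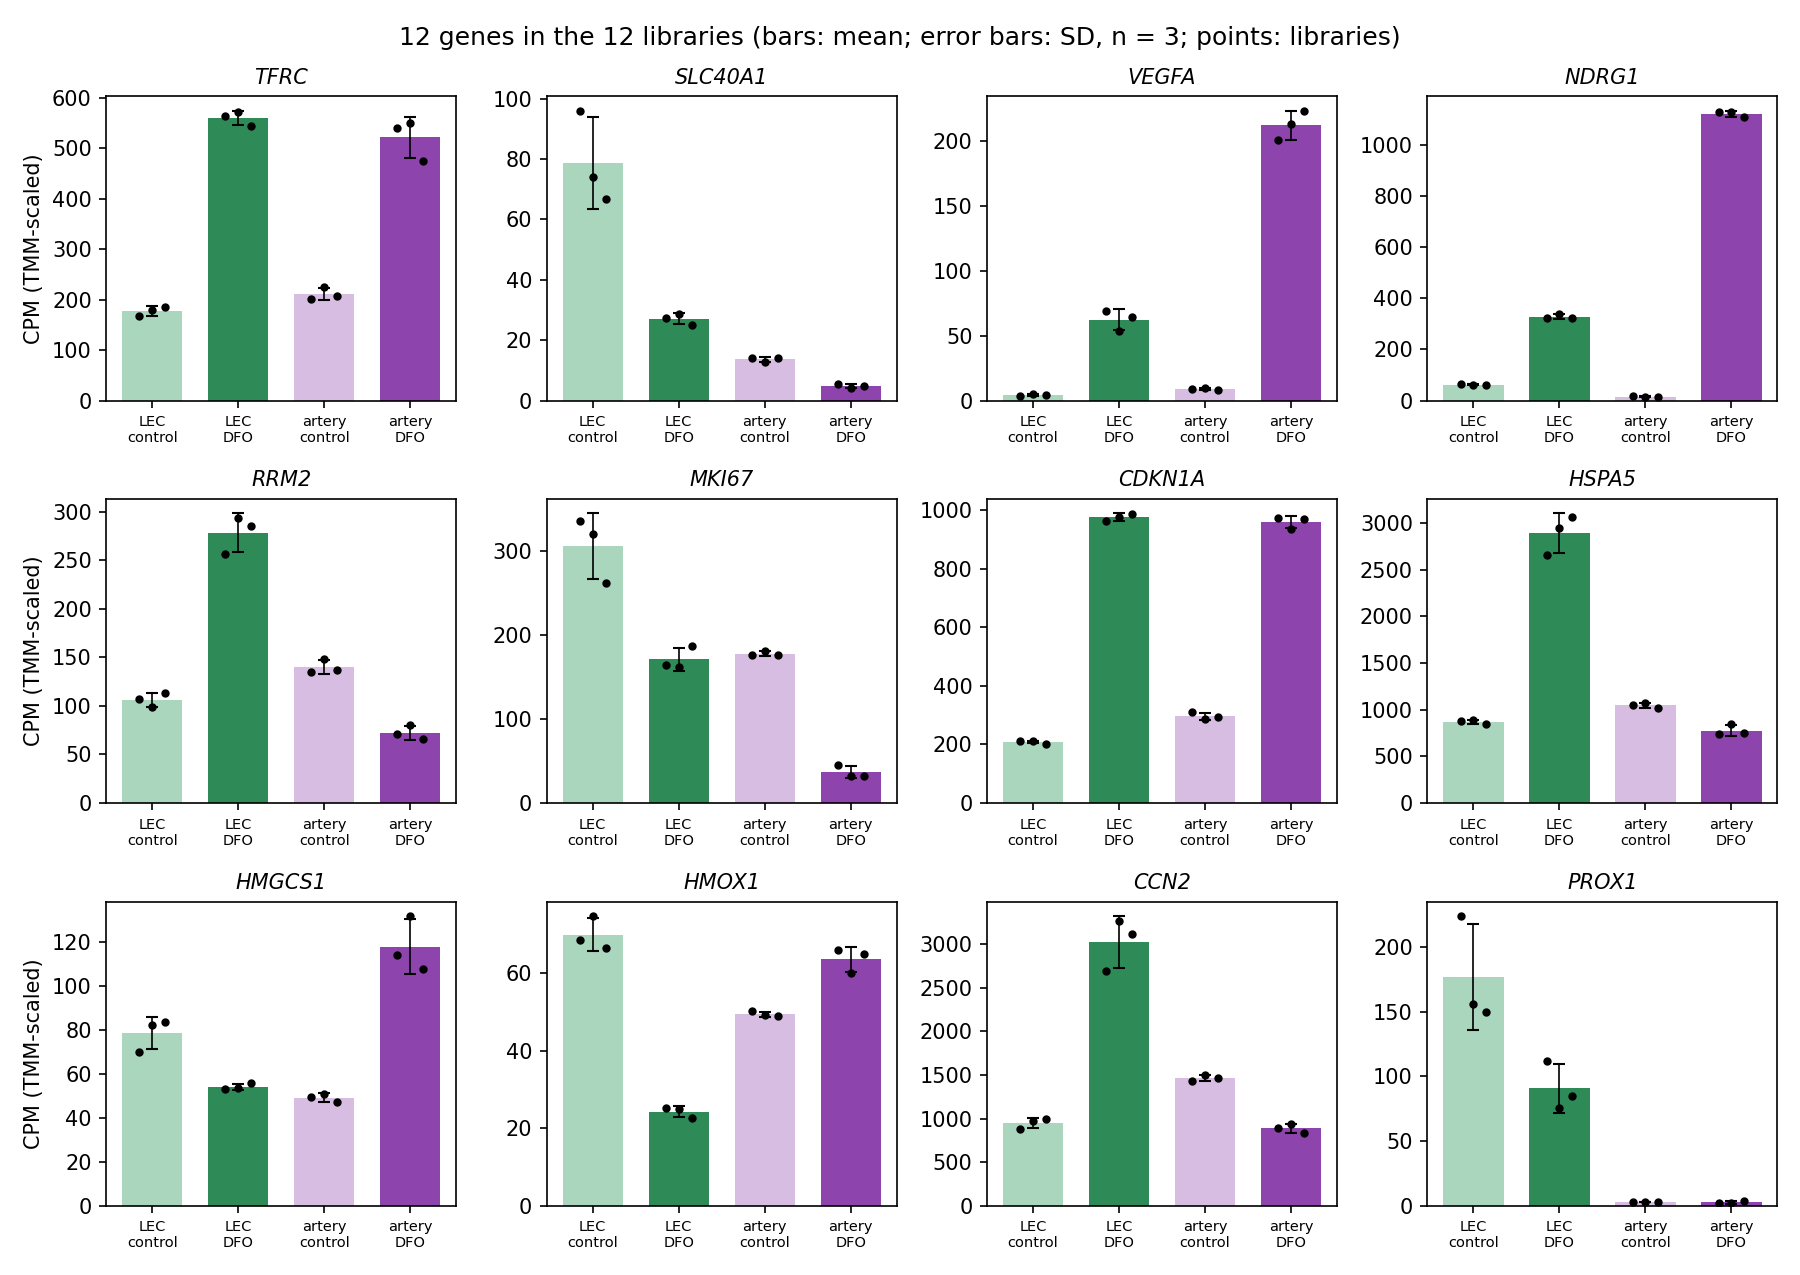
TMM-scaled CPM of 12 genes in the 12 libraries by group, with bars at the mean, error bars of SD (n = 3) and a point per library, each axis from 0. TFRC rose from 177 to 560 CPM in LEC and from 212 to 521 in artery EC, while RRM2, HSPA5, HMGCS1, HMOX1 and CCN2 moved in opposite directions in the 2 cell types. For HMOX1 the artery rise (0.36 on the log2 scale) depends on the scaling, being no larger than the shift of the median gene under total counts (-0.38).

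Without DFO, the cell types carried the marker genes of their names. LEC control expressed 16 of 20 lymphatic genes above artery control, and MMRN2 below (median 1.97, adjusted p = 1.34e-06, and adjusted p = 0.265 with an estimated correlation). PDPN, the lymphatic membrane glycoprotein podoplanin (ENSG00000162493, chromosome 1, 13583465 to 13617957), stood at 332 CPM in LEC and had 0 counts in artery EC, at least 10100-fold higher, and CLDN11, RELN and SEMA3D were higher by 7.0, 5.85 and 5.71. Artery control expressed 19 of 26 arterial genes above LEC, and 5 were higher in LEC (SOX7, HEY1, JAG1, NRP1 and TM4SF1; median -1.03, adjusted p = 0.00103, and adjusted p = 0.51 with an estimated correlation). GJA5, the arterial gap junction gene connexin 40 (ENSG00000265107, chromosome 1, 147756199 to 147773362), was at 29.1 CPM in artery EC and 0.0924 in LEC (-8.17 ± 0.28, adjusted p = 1.11e-21), BMX and CXCR4 differed by -2.29 and -2.05, and HEY1 was higher in LEC by 3.45. The LEC level of GJA5 rests on 7 counts, so its SE is likely too small. Inflammation genes were lower in LEC in 19 of 25 cases, with CXCL8 and NFKB1 higher (median -1.69, adjusted p = 1.26e-05). Mitosis genes were higher in LEC in 23 of 28 cases and CDC20 lower (median 0.54, adjusted p = 0.00103, and adjusted p = 0.51 with an estimated correlation). The pan-endothelial, angiogenesis, interferon and ER stress lists were lower in LEC in 15, 15, 16 and 12 members and higher in 7, 7, 5 and 3, with adjusted p-values of 0.0364, 0.0404, 0.0364 and 0.0364, and adjusted p-values of 0.689, 0.685, 0.6 and 0.6 with an estimated correlation. All these counts were the same adjusted over the list alone. No other list was called. Their medians and means differed in sign for mitochondrially encoded genes, dioxygenases, matrix, autophagy and ribosome biogenesis.

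In the control comparison, 5544 genes were higher and 4861 lower in LEC, a balance that turned with upper-quartile scaling (4650 and 5662), total counts (5126 and 5207), the controls fitted alone (5205 and 5211) or with a replicate block (5212 and 5242), and the test against 1.5-fold (2012 and 2447). Besides PDPN, the largest by the naming rule were TFF3, HOPX, PLCXD3 and ESX1, with 0 counts in artery control and at least 1830-fold, 1780-fold, 1590-fold and 1170-fold higher in LEC. Lower in LEC were SHISA3 and TNC, with 0 counts there and at least 311-fold and 300-fold lower, and RGS7BP, NUP210 and ABCB1, with 1 or 2 counts and ratios of 1280 (95% interval 230 to 50600), 895 (248 to 7400) and 813 (225 to 6720).

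The authors' deposited tables call 4541 genes higher and 3953 lower with DFO in LEC and 5076 and 4801 in artery EC, among 17141 genes. Over 15940 genes in both sources, their log2 fold changes correlated with those here at 0.997 in LEC and 0.998 in artery EC, across genes. Of the genes called in both sources, 8055 in LEC and 9631 in artery EC, each had the same sign.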

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

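Chosen only after the result was seen were the tests of depth, scaling and dividing cells on the division genes, of scaling on the cholesterol genes, and of starting levels on the hypoxia targets. All results of this part were picked because the DFO effect in LEC and in artery EC differed by the direct test (LEC effect minus artery effect, log2 scale), which called 5356 genes. The bootstrap intervals treat list members as independent and hold no spread between libraries, so they are likely too narrow. The estimated correlation between genes was 0.273 for cholesterol synthesis, 0.149 for mitosis and 0.124 for DNA replication.

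Mitosis genes fell less in LEC, and DNA replication genes fell in artery EC and split in LEC, with median differences of 1.5 for DNA replication and 2.08 for mitosis (2.07 with few-count genes left out). After thinning to equal totals the median over the 56 members was 1.88 (95% bootstrap interval over members 1.72 to 1.97). Thinning leaves each gene's expected share of the counts unchanged. It could therefore hardly have removed the pattern, and nothing is concluded on depth. The smallest median over 4 scalings was 1.90 (1.73 to 1.99), so none of them accounts for the pattern. They put the median gene's difference only between -0.018 and 0.10, so this check could not have removed the pattern and says nothing of scaling beyond them. More dividing cells in artery EC before DFO would put the members lower in LEC control. A bound of 1 on the log2 scale for this was set after the result was seen. Mitosis genes were instead higher there by 0.54 (0.43 to 0.73), while replication genes were slightly lower, at -0.20 (-0.33 to -0.008). An excess below that bound therefore stays open, with the lists pointing opposite ways. A different response of the cell types to DFO may account for the pattern, as a hypothesis found and tested on the same data, but culture and donor differences between the cell types were not tested.

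Of 24 cholesterol synthesis genes, 18 rose and 2 fell in artery EC, and 5 rose and 12 fell in LEC, with a median difference of -0.89, although the list's call was lost with an estimated correlation in artery EC (adjusted p = 0.186) and for the difference (0.106). GC content and gene length, known for 99.9% of genes and explaining 0.716% of the variance of the difference, left -0.94 (-1.24 to -0.67) once removed. Of 4 scalings, the value nearest to 0 was -0.78 (-1.20 to -0.60), with total counts. Neither the trend nor these scalings account for the pattern. The trend was weak, and the scalings put the median gene's difference only between -0.018 and 0.10, so neither check could have removed the pattern and nothing further is concluded. A difference in response remains a hypothesis that may also reflect the cultures, which were not tested.

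Hypoxia targets rose by more in artery EC, with a median difference of -1.03. Removing the trend on GC content and length left -1.04 (-1.18 to -0.82), a check that could change little, as the trend explained 0.716% of the variance. Lower starting levels in artery EC are argued against for the list as a whole, since LEC control minus artery control had a median of -0.23 (-0.70 to 0.10). This does not cover single members: 9 of 32 were higher in LEC control and 14 lower. NDRG1 stood at 61.9 CPM in LEC control and 15.1 CPM in artery control, so a lower start stays open for it. A larger response of artery EC across all genes stays open: the spread of effects outside the list was 1.33 times that in LEC, and after allowing for it a median of 0.44 was left (0.005 to 0.65), an interval that spans the bound of 0.25 set beforehand. This pattern may therefore be part of a generally larger response, and the explanations cannot be told apart for these 30 members.

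The other lists that differed had median differences of 0.31 for iron-sulfur and heme synthesis, -0.47 for glycolysis, 0.41 for nuclear oxidative phosphorylation, 0.38 for the TCA cycle, 0.56 for p53 targets, -0.59 for dioxygenases, -0.12 for matrix (-0.11 with few-count genes left out), 0.50 for inflammation (0.40 with few-count genes left out), -0.28 for autophagy and 0.20 for ribosome biogenesis. With an estimated correlation only the dioxygenases kept their call (adjusted p = 0.0141), and the other 9 had adjusted p-values from 0.0647 to 0.309. Of the 30 dioxygenases, 10 are also on other lists, among them the hypoxia targets EGLN1, EGLN3, P4HA1, P4HA2, KDM3A and JMJD6, so this call partly repeats that of the hypoxia targets. The inflammation median was 0.23 without artery control replicate 2 and 0.27 without LEC DFO replicate 2, and the matrix median -0.079 without artery DFO replicate 1. Leaving out ABCB1, KBTBD11 and SLITRK4, which had 3 counts or fewer in a group, the largest single differences were 4.62 for MGARP, 4.28 for TMEM171, which had 4 counts in LEC control, 3.90 for DEPDC1, 3.75 for SPC25, 3.56 for DKK1, 3.50 for FST, 3.28 for UBE2C, -4.04 for MIR210HG, -3.95 for SYTL2, -3.80 for NDRG1, -3.54 for KCTD16, -3.52 for ZSWIM5 and -3.22 for DTNA. Of 193 genes picked by the naming rule for either DFO comparison, 133 differed, and 15 were called in opposite directions. Among them, RRM2 (2.34), CDT1 (2.04), HSPA5 (2.17), CCN2 (2.40) and MYL9 (1.26) rose in LEC and fell in artery EC, and HMOX1 (-1.90), HMGCS1 (-1.80), SLC7A11 (-1.39), CLDN5 (-1.46), KDR (-0.75), HEY1 (-2.10), INSIG1 (-2.10), SQLE (-1.68) and POSTN (-1.07) did the reverse. Of these, the artery call of KDR depends on the library and turned direction under total counts (-0.20), and that of HEY1 was lost without artery control replicate 1 (adjusted p = 0.0527) and under total counts (0.441). For the artery rises of HMOX1 (0.36) and CLDN5 (0.25) and the LEC rise of MYL9 (0.35), the values under total counts were not recorded. The median gene then stands at -0.38 in artery EC and -0.28 in LEC, so those artery rises depend on the scaling and that of MYL9 would be smaller.

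Other splits of the same libraries were tested. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05: the real split called 8490 genes in LEC, 10065 in artery EC and 10405 between controls, 1 split of 10 each, and the highest other split called 0. For lists the real split called 14 in LEC, reached by 3 of 10 splits with a highest other of 17, and 19 in artery EC, reached by 1 of 10 with a highest other of 18. Every other split called at least 9 lists in LEC and 11 in artery EC, though none called a gene. Each of these other splits mixes DFO and control libraries unevenly, so it holds part of the DFO effect by construction. They therefore cannot show whether camera with the preset correlation calls lists too easily, which stays open. The list p-values still call for caution. For the 5938 genes called in both cell types in the same direction, 1 of 100 splits gave as many and the highest other gave 0, but this decides nothing, since no other split of either cell type alone called a gene. For the difference, 6 of 100 splits gave at least 5356 genes, the highest other 5841, so chance is not excluded by this count. The 5 others were among 23 splits that kept DFO and control apart within a cell type and called 96 to 5841 genes, which points to the structure of the samples, while the 76 splits that mixed both called 0. For lists of the difference, 34 of 100 splits reached 14, with a highest other of 19. The other splits of the difference also hold all or part of the DFO effect in each cell type. They set no level for chance, so chance is not excluded and nothing further is concluded.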

How the results depend on the processing

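Thinning to equal depth was chosen only after the depths were seen, and all other alternatives were fixed before the data were examined. The counts of called genes stayed within 1.5 times the reported ones except as follows, and the cause was not tested unless it follows from the setting. With total counts, LEC had 2406 higher and 6701 lower and artery EC 2788 and 7657, as the median gene shifts. The test against a 1.5-fold change, stricter by construction, called 1239 higher and 1333 lower in LEC, 2204 and 2309 in artery EC, 1256 for the difference, 4459 between controls and 1605 in both cell types. The correlation of the effects was 0.241 without a filter, 0.655 with CPM at least 1 in 3 libraries, 0.620 with limma-voom, 0.692 with each comparison fitted alone, and 0.538 to 0.583 when a library was left out. Every setting refitted all genes, but single values were recorded only for genes that the naming rule picked for a comparison. Among these, the sign turned under total counts for KRT18 (-0.21) and FTH1 (-0.25) in LEC, and for MT-ND5 (-0.032), MT-CO1 (-0.11), KDR (-0.20) and FLT4 (-0.092) in artery EC. For HMOX1 and CLDN5, also reported as rising in artery EC, the values under total counts were not recorded, and their rises are smaller than the shift of the median gene. When a library of the compared groups was left out, LEC had 3838 to 4118 higher and 3777 to 4034 lower, artery EC 4891 to 4977 and 4643 to 4689, the difference 4588 to 5490, the controls 9754 to 9996 and both cell types 5448 to 5852. Leaving out a library of another group gave at most 4355 and 4391 in LEC and 5252 and 5042 in artery EC, and for the controls at most 5712 higher and 5156 lower. Of the reported calls tested again, none turned direction in any setting except 114 of 10065 in artery EC under total counts. The call of SLITRK4 for the difference was lost in 6 settings and without any of 10 libraries, and that of ABCB1 without LEC DFO replicate 1 or 2 or LEC control replicate 2 or 3, both with few counts. With an estimated correlation 29 list calls of the LEC, artery and difference comparisons were lost. Without a low-count filter 6 were gained, among them arterial identity (adjusted p = 0.0228), mesenchymal transition (0.0275) and smooth muscle markers (0.0373) in LEC and pan-endothelial identity (0.0232) in artery EC, and under total counts mesenchymal transition was gained in LEC (0.0365). Of 29 lists, fry's PValue called 21 in LEC, 26 in artery EC and 19 for the difference, and PValue.Mixed called 29 in each. Whether the replicate number pairs the samples is not known: same-numbered DFO and control libraries correlated at 0.2, 0.113 and -0.082 in LEC and 0.194, 0.29 and -0.095 in artery EC, and some but not all samples correlated best with their own number. With 3 libraries per group, taken as deviations from the group mean, this check cannot exclude pairing. With the number as a block, LEC had 4347 and 4362 genes, artery EC 5174 and 5005, the difference 5706 and the controls, fitted apart from the DFO libraries, 10454. It changed 2 list calls of the difference, pan-endothelial (adjusted p = 0.0416, gained) and inflammation (adjusted p = 0.0618, lost), and no call of a named gene. Depth limits genes with 3 counts or fewer over a group, 0.0328 to 0.058 CPM.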

Other observations

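No test in this part was chosen after its result was seen, but the genes named in it were picked after their values were seen, apart from DKK1, FST and MGARP. Before DFO, venous genes were divided between the cell types. NR2F2, EPHB4, NRP2, FLRT2 and TLL1 were higher in LEC control, FLRT2 by 2.0 on the log2 scale, whereas CPE, VWF, SELP, CCL14 and POSTN were lower, POSTN at -4.41, so that 5 of 10 tested genes went each way (camera adjusted p = 0.856). The pericyte gene RGS5, which some EC also express, was at -3.74 in LEC against artery control, and the platelet-adhesion gene VWF at -1.53. The chemokine gene CXCL8 was higher in LEC control by 1.07 while 19 other inflammation genes were lower.

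Several further genes changed differently in the cell types with DFO. The secreted Wnt inhibitor gene DKK1 went from 6.93 to 30.7 CPM in LEC and from 92.8 to 34.7 CPM in artery EC, and FST, which encodes the activin antagonist follistatin, from 4.97 to 17.1 and from 39.4 to 12.1 CPM. For both genes the DFO groups of the cell types lay closer to each other than the control groups did. MGARP, a mitochondrial protein gene that shares 29.4% of its exonic bases with NDUFC1 on the same strand, went from 1.58 to 4.54 CPM in LEC and from 34.1 to 3.91 CPM in artery EC. Among list members, the gap junction gene GJA4 fell further in artery EC than in LEC (difference 1.14), and the metalloprotease inhibitor gene TIMP3 had a higher effect in LEC by 3.02.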
